A study of Mus musculus with 77 samples.

How the data were processed

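RNA abundance was measured on 77 arrays from testes of neonatal mice that carry a RiboTag allele, a ribosomal protein gene whose product gains an epitope tag after Cre recombination. In the Stra8-cre and Ngn3-cre lines the tag marks ribosomes of germ cells, and in the Amh-cre line it marks those of Sertoli cells. Total RNA was taken from the whole testis, and immunoprecipitated (IP) RNA is the polysome-associated RNA recovered with the tagged ribosomes. Per the labels' protocols, the animals were given the retinoic acid synthesis inhibitor BDAD (a bis-dichloroacetyl diamine) for 9 days and were then either killed (time 0) or injected with retinoic acid (RA). RNA was extracted with RNeasy columns, amplified to cDNA with the Ovation V2 kit and labelled with the Encore biotin module.

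The deposited values are RMA intensity on a linear scale, from a gene-level Affymetrix array with 1 colour. RMA is named in the submitters' processing notes. Its software, version, background and normalization settings, the arrays processed together and the step back to a linear scale are not given in the sources used here. Array medians lay between 252.6 and 300.5 intensity units and the smallest values between 25.1 and 26.3, so low intensities are compressed towards a floor. The log2 of each value was taken with no other scaling. Of 28853 probe sets in the values, 23410 were listed with a gene and 5443 were not listed and were left out, as were 1621 listed with several genes. Genes were matched by gene number for 99.6% of the probe sets, and 0 symbols changed. Where a gene had more than 1 probe set (999 genes), the one with the highest mean was used, leaving 19938 genes tested. All arrays were used. Their depth has no count, and precision is limited by the number of arrays and, for low signals, by the floor.

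The labels gave 35 groups by line, fraction and labelled time, of which 31 held 2 arrays, 1 held 3 and 3 held 4. A single limma 3.58.1 model in R 4.3.3 (with data.table version 1.17.8) gave each group its own mean over all 77 arrays, so groups of 2 share one estimate of the spread, with empirical Bayes moderation and an intensity trend. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its difference at least 2-fold (log2 of 1). The 26 comparisons were IP against total RNA in each line (mean over the times with both), Stra8 against Amh in each fraction, every time against 0 in IP RNA, moderated F tests over each time course, and the differences between lines in the response. For an F test the 2-fold minimum applied to the largest difference at any time, and values printed for a course are that difference. Tests of genes and of lists were two-sided, and tests of shared calls were one-sided. Nothing in the labels says that replicates came from separate animals, so the p-values measure the spread between these samples. Replicate numbers were tested as pairs by the correlation of residuals, with a minimum of 0.1. Of 17 pairs of IP and total groups 13 passed it (correlations from -0.27 to 0.585), including every pair of the Amh line. Of 56 pairs of times 9 passed, so times were not paired.

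For cell types and pathways, 18 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. They were germ cell and piRNA pathway, undifferentiated spermatogonia, differentiating spermatogonia, meiotic entry and prophase, pachytene and spermatid, RA-induced targets, RA synthesis and transport, Sertoli cell, cell junction components, Sertoli niche factors, Leydig cell and steroidogenesis, peritubular myoid, macrophage, endothelial, erythroid, mitosis, DNA replication and immediate early genes. Named genes were the 6 called genes with the largest difference in each direction for fractions and lines, 3 in each direction for a time, and 8 for a course, among genes whose groups' arrays did not overlap and leaving out predicted or clone symbols. Up to 4 members per list and comparison were added, with Stra8, Kit, Rec8, Cyp26a1, Rarb, Dhrs3, Sycp3, Zbtb16, Ddx4, Amh, Sox9, Cyp17a1 and Acta2 in any comparison. Groups, comparisons, tests, lists, the naming rule and the first set of alternative settings were fixed before the data were examined.

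That first set was no fold minimum, a camera correlation estimated from the data, the 30% of genes with the lowest signal left out, median centring, quantile normalization, the mean of a gene's probe sets, the replicate number as a block, the compared groups alone, and each array left out in turn. Added after seeing the data were fits without the Amh arrays labelled 4h and 4d, without 3 arrays of narrow signal range, and without the Stra8 total arrays labelled 4h. In comparisons of at least 3 arrays per arm, 100 splits were drawn by exchanging the arms within each time (18 for Ngn3). The fit was tested on simulated data with 200 changed genes in 4 comparisons. Of 50 genes changed 3-fold and 50 changed 4-fold, all were called in each of the 4. Of 50 changed 2-fold, at the fold minimum itself, 18 to 24 were called, and 0 unchanged genes were called. The simulated noise was independent between genes and between arrays. Real arrays can differ in many genes at once, so the 0 does not bound false calls in the real data.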

Results

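The series follows gene expression in germ cells and Sertoli cells of the neonatal mouse testis after a block of retinoic acid synthesis is ended by an injection of RA. IP RNA was drawn from germ cells in the Stra8-cre line (16 IP arrays, with 23 of total RNA) and the Ngn3-cre line (4 IP and 4 total arrays), and from Sertoli cells in the Amh-cre line (16 IP and 14 total arrays), while total RNA holds all cells of the testis. Stra8 and Amh arrays were labelled 0, 4h, 12h, 24h, 48h, 4d, 6d and 8d after RA, and Ngn3 arrays 0 and 4h. Amh total RNA at 4h was not analysed here. Groups held 2 arrays except Stra8 total at 4h (3) and at 0, 24h and 48h (4 each). Stra8 and Amh animals were FVB/N and Ngn3 animals C57BL/6, so line and strain cannot be separated for Ngn3. Log2 intensities of arrays in the same group correlated across genes with r between 0.958 and 0.999 (median 0.995; genes are not independent replicates). Changes below are log2 differences with the SE of the fit. No array came from animals given a vehicle or left uninjected for the same time after BDAD. A change from time 0 can therefore follow from RA, the injection, age or the end of BDAD, which cannot be told apart. The word response below means such a change. For all 26 comparisons, counts were larger when the 2-fold minimum was left out.

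IP against total RNA in the Stra8 line asks which RNAs the germ cell tag recovers. Germ cell genes were enriched: Tex19.1, a germ cell protein that restrains transposons, was 3.56-fold higher in IP RNA (log2 1.83 ± 0.05, adjusted p = 3.09e-35, 16 IP and 23 total arrays). Magea5 was higher by 2.30 ± 0.11, Piwil4, which guides piRNA-directed DNA methylation, by 1.67, and Tdrd1, a scaffold of the piRNA pathway, by 1.64. The spermatogonial regulators Sall4 (1.56), Sohlh1 (1.44) and Pou5f1 (1.63) were enriched too. Somatic genes were depleted, led by the Sertoli cell cystatins Cst9 (-3.01 ± 0.08, adjusted p = 3.66e-34) and Cst12 (-2.77), with Amh, the Sertoli hormone that regresses the Müllerian duct, at -2.16 ± 0.10 (adjusted p = 7.92e-25). Depletion also reached Cyp11a1 (-2.32) and Cyp17a1 (-2.03) of Leydig cell steroidogenesis, Acta2 (-1.90) of peritubular myoid cells, Lyz2 (-2.55) of macrophages and Cd34 (-1.92) of endothelium. In all, 766 genes were higher and 1071 lower in IP RNA. IP minus total for the germ cell and piRNA list (mean log2) was 1.748 at time 0 and 0.847 at 8d. Over that span the list went from 11.45 to 11.21 in IP RNA and from 9.70 to 10.36 in total RNA. Which germ cells carried the tag at each time was not measured. Changes over time in Stra8 IP RNA cannot be told apart from a changing mix of tagged cells.

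By list, 15 of 19 measured germ cell and piRNA pathway genes were higher in Stra8 IP RNA (median 1.37) and 0 were lower (camera adjusted p = 3.84e-09; adjusted p = 0.135 with an estimated correlation). Undifferentiated spermatogonia genes were higher for 12 of 25 members (adjusted p = 0.0612 with an estimated correlation), differentiating spermatogonia genes for 7 of 16 (adjusted p = 0.168 with an estimated correlation) and meiotic entry and prophase genes for 12 of 33 (adjusted p = 0.219 with an estimated correlation). Dividing-cell lists were enriched as well, mitosis for 11 of 19 members (adjusted p = 0.154 with an estimated correlation) and DNA replication for 10 of 20 (adjusted p = 0.153 with an estimated correlation), among them Bub1b (1.55), a spindle checkpoint kinase, and Mcm6 (1.42), a subunit of the replicative helicase. Sertoli cell genes were lower for 26 of 31 members (median -1.93, adjusted p = 4.39e-18; adjusted p = 0.0612 with an estimated correlation). Leydig cell genes were lower for 10 of 13 (adjusted p = 0.0612 with an estimated correlation), myoid genes for 7 of 12 (adjusted p = 0.0612 with an estimated correlation), macrophage genes for 10 of 13 (adjusted p = 0.135 with an estimated correlation) and endothelial genes for 4 of 11 (adjusted p = 0.082 with an estimated correlation). Sertoli niche factors were lower for 8 of 18 members (adjusted p = 0.082 with an estimated correlation) and cell junction components for 4 of 19, with 1 higher (adjusted p = 0.219 with an estimated correlation). Lists that did not pass were pachytene and spermatid (2 higher and 1 lower of 25, adjusted p = 0.182), RA-induced targets (1 and 6 of 18, adjusted p = 0.197), RA synthesis and transport (0 and 3 of 13, adjusted p = 0.201), erythroid (0 of 4, adjusted p = 0.63) and immediate early genes (0 and 1 of 14, adjusted p = 0.72). Adjusted over the list alone, every one of these counts was the same.

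In the Ngn3 line, of another strain, the same contrast also enriched germ cell genes. Fndc3c1 was 7.08-fold higher in IP RNA (log2 2.82 ± 0.18, adjusted p = 1.84e-18, 4 IP and 4 total arrays), Dnmt3l, a cofactor of germ cell DNA methylation, was higher by 2.52 ± 0.13, and the piRNA factors Tdrd9 (2.20) and Piwil4 (2.12) were enriched. Utf1 (1.74), Zbtb16 (1.20), which maintains spermatogonial stem cells, Ddx4 (1.12) and Sycp3 (1.49) were also higher. Cst9 (-2.97), Amh (-2.59 ± 0.22), Sox9 (-1.81), the transcription factor of Sertoli identity, and Acta2 (-1.98) were lower. Germ cell and piRNA genes were higher for 16 of 19 members (median 1.68; adjusted p = 0.0958 with an estimated correlation) and Sertoli cell genes lower for 25 of 31, with 2 higher (median -1.85; adjusted p = 0.0831 with an estimated correlation). The same counts were found adjusted over the list alone. Of 1233 genes higher and 1345 lower in Ngn3 IP RNA, 684 and 909 were called in the same direction in the Stra8 line.

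In the Amh line the same contrast asks what the Sertoli cell tag recovers. Germ cell RNA was depleted: Mael, a piRNA pathway protein, was lower by 7.98-fold in IP RNA (log2 -2.996 ± 0.05, adjusted p = 5.05e-42, 14 arrays of each fraction at the 7 times compared). Sycp3, a component of the synaptonemal complex, was at -2.86, Ddx4, a germ cell RNA helicase, at -2.51 ± 0.07, Kit at -1.94 and Stra8 at -1.66. Amh itself was 2.61-fold higher (1.39 ± 0.12, adjusted p = 4.14e-15), as were Gata1 (1.25 ± 0.07), a Sertoli cell transcription factor in the testis, Tubb3 (1.59), Vasn (1.54) and Rnf138rt1 (1.65). Other somatic cells were depleted, with Cyp11a1 at -2.49, the contractile protein gene Cnn1 at -1.69, Lyz2 at -2.41 and Cd34 at -2.60. The test called 220 genes higher and 785 lower, and 1005 genes in all with the replicate number as a block.

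Germ cell and piRNA genes were lower for 16 of 19 members in Amh IP RNA (median -1.81, adjusted p = 6.04e-20; adjusted p = 0.0279 with an estimated correlation), and peritubular myoid genes for 8 of 12 (median -1.30; adjusted p = 0.0279 with an estimated correlation). Meiotic entry and prophase genes were lower for 21 of 33 (adjusted p = 0.068 with an estimated correlation) and mitosis genes for 14 of 19 (median -1.10; adjusted p = 0.068 with an estimated correlation). The mitosis value averages over unlike times: IP minus total (mean log2 of the list) was 0.014 at time 0, -1.855 at 48h, -0.085 in the arrays labelled 4d and -1.89 at 6d. Sertoli cell genes passed the list test (median 0.62 against 0.116 for all genes, adjusted p = 2.43e-05; adjusted p = 0.296 with an estimated correlation), though only 3 of 31 members passed the 2-fold minimum. These counts were the same adjusted over the list alone. The balance of directions for Amh IP versus total RNA depended on the scaling, since median centring gave 534 genes higher and 597 lower.

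Stra8 against Amh IP RNA sets the germ cell fraction against the Sertoli cell fraction over the 8 times. Slc25a31, a germ cell ADP/ATP carrier, was 16.8-fold higher in the Stra8 line (log2 4.07 ± 0.08, adjusted p = 1.04e-41, 16 arrays each). Asz1 (3.94), Sycp3 (3.84), Ddx4 (3.51), Sall4 (3.36) and Kit (2.86), the receptor of stem cell factor on differentiating spermatogonia, followed. Cst9 (-3.84), Amh (-3.55 ± 0.11), Gata1 (-3.22), Sox9 (-2.49) and Cldn11 (-2.57), a tight junction claudin, were higher in the Amh line. Germ cell and piRNA genes were called for 19 of 19 members (median 3.11; adjusted p = 0.106 with an estimated correlation), Sertoli cell genes lower for 27 of 31 (median -2.47; adjusted p = 0.106 with an estimated correlation) and junction components lower for 11 of 19, with 1 higher (adjusted p = 0.198 with an estimated correlation). Mitosis genes were higher in the Stra8 line for 17 of 19 members (adjusted p = 0.106 with an estimated correlation), including Bub1 (2.88). The list counts did not move adjusted over the list alone. The comparison called 1503 genes higher and 1846 lower.

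Total RNA of the same lines, the background for that contrast, differed for 6 genes: Vnn1 (1.98 ± 0.14), Serpina3a (1.86), Fam181b (1.76) and Frzb (1.63) were higher in the Stra8 line, and Cpa3 (-1.10), a mast cell protease, and Ephb1 (-1.04) lower. Ephb1 lost its call with the mean of its probe sets (-0.74), without Stra8 total 6d replicate 2, without Amh total 6d replicate 1 and without the Amh arrays labelled 4h and 4d (-0.99). No member of any list was called, over all genes or adjusted over the list alone. Camera placed the macrophage list higher in the Stra8 line (median 0.25; adjusted p = 0.596 with an estimated correlation) and the mitosis list lower (median -0.19; adjusted p = 0.596 with an estimated correlation).

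The first hours after RA were read in Stra8 IP RNA at 4h. Cyp26a1, the enzyme that degrades RA and a direct target of its receptors, rose 7.49-fold, from 89.5 ± 0.919 to 672 ± 68.6 intensity units (SD, n = 2 each; log2 2.91 ± 0.43, adjusted p = 9.22e-06). Rarb, an RA receptor induced by RA, rose by 2.21 ± 0.25 (adjusted p = 2.82e-08), Stra8, which drives spermatogonial differentiation and meiotic entry, by 2.10 ± 0.38 (adjusted p = 0.000396), and Tgm2, a transglutaminase, by 1.26 ± 0.25. Nr0b1 (2.01 ± 0.31), on the Sertoli cell list, and the smooth muscle myosin gene Myh11 (1.33 ± 0.18), on the peritubular myoid list, rose as well. Mean log2 at time 0 and 4h was 10.08 and 10.00 for the Sertoli cell list, and 9.21 and 9.24 for the myoid list. Whether these genes rose in germ cells or in somatic RNA recovered with the IP was not tested. Of 18 RA-induced targets, 5 rose (list median 0.25, adjusted p = 7.22e-11; adjusted p = 0.000199 with an estimated correlation), the same number adjusted over the list alone. In all, 46 genes rose and 2 fell.

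Ngn3 IP RNA at 4h asks whether germ cells of a second line respond alike. Cyp26a1 rose 13.6-fold (log2 3.76 ± 0.43, adjusted p = 1.14e-08, n = 2 each), Rarb by 2.09 ± 0.25 (adjusted p = 5.42e-08) and Cplane2, a ciliogenesis gene, by 2.51 ± 0.17 (adjusted p = 3.63e-15), while Il20ra fell by 1.28. RA-induced targets rose for 3 of 18 members (median 0.39; adjusted p = 0.00136 with an estimated correlation), and for 3 adjusted over the list alone. Of 56 genes that rose in Ngn3 and 46 in Stra8 IP RNA, 26 were shared, against 0.129 by chance (Fisher's exact test, one-sided, p = 2.4e-57). Across all genes the 4h changes in the lines had a Pearson correlation of 0.25. Another 6 genes fell in Ngn3 IP RNA. The total of 62 became 123 without Ngn3 IP 0 replicate 2. In a direct test of the difference between the responses limma called 0 genes, with 1991 at an unadjusted p under 0.05, which does not show that the responses were alike. That count was 2 with quantile normalization and rose above 0 in 7 of 8 fits that left out 1 array, to between 1 and 3 in 6 of them and to 41 without Ngn3 IP 0 replicate 2.

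**Figure D1:**
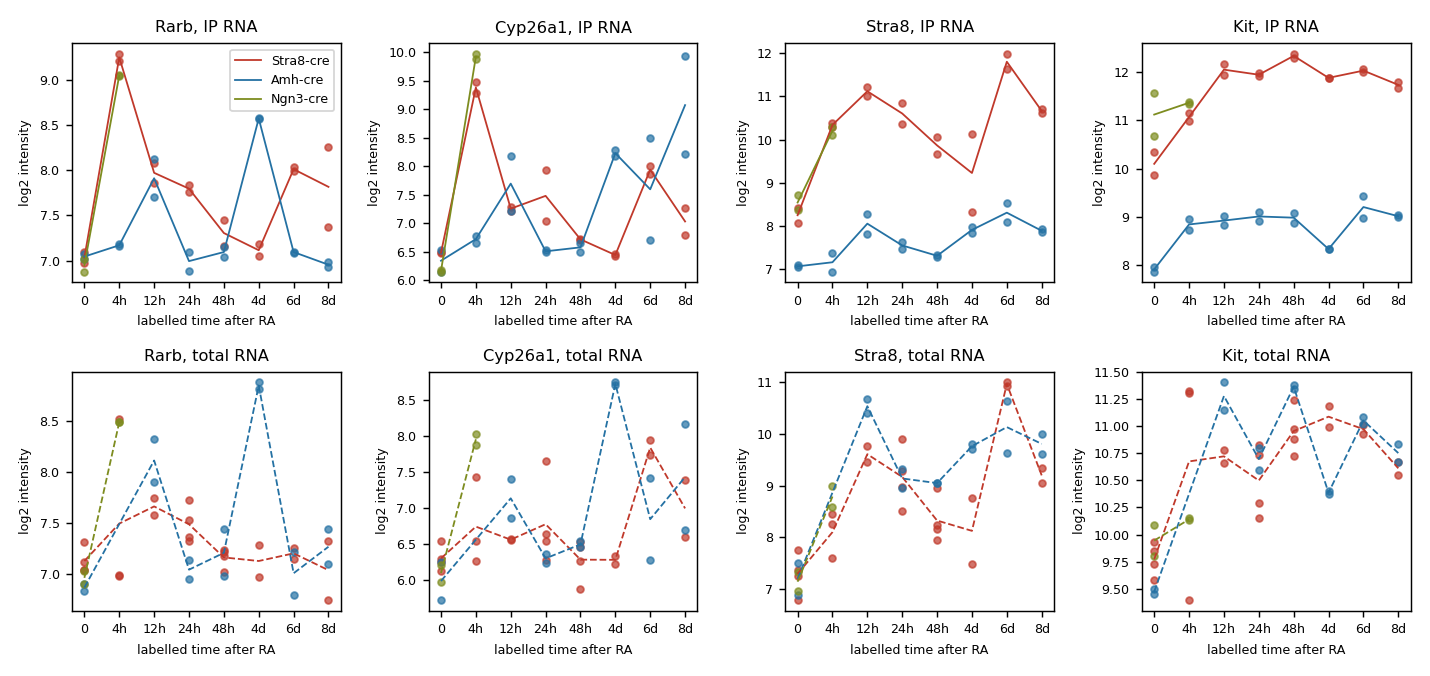
Log2 intensity of Rarb, Cyp26a1, Stra8 and Kit (vertical axes) against labelled time after RA, with IP RNA in the top panels and total RNA in the bottom panels; points are arrays, lines join group means and colours are the lines. Rarb stands at 9.25 in Stra8 IP at 4h, at 7.17 in the Amh IP arrays labelled 4h and at 8.57 in those labelled 4d.

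From 12h to 48h, Kit rose in Stra8 IP RNA while the list of undifferentiated spermatogonia genes fell. Kit rose by 1.95 ± 0.29 at 12h (adjusted p = 5.47e-06), 1.85 at 24h and 2.24 at 48h (adjusted p = 2.45e-07), and Stra8 by 2.87 ± 0.38 at 12h and 2.36 at 24h. The transcription factor genes Tbx1 (1.91 at 24h, 2.59 at 48h) and Dlx1 (2.44 at 48h) rose too. Six4 fell at 12h (-2.03) and 24h (-2.19), and Etv5 (-1.37) and Lhx1 (-1.47), which respond to GDNF in stem cells, fell at 12h, as did Egr2 (-1.83). Pou5f1 (-1.53) and Upp1 (-1.20) fell at 48h. Undifferentiated spermatogonia genes fell for 4 of 25 members at 12h (median -0.38; adjusted p = 0.0118 with an estimated correlation), 1 at 24h (median -0.54; adjusted p = 0.005 with an estimated correlation) and 2 at 48h (median -0.65; adjusted p = 0.0112 with an estimated correlation). Adjusted over the list alone, the count at 48h was 3 and the others were the same. Differentiating spermatogonia genes rose for 2 of 16 at 12h and at 24h (adjusted p = 0.342 and adjusted p = 0.494 with an estimated correlation), and the list did not pass at 48h (2 of 16 higher, adjusted p = 0.116), with as many adjusted over the list alone. DNA replication genes moved up at 12h with no member called (median 0.45; adjusted p = 0.11 with an estimated correlation). The Sertoli cell list stood lower at 48h (median -0.44; adjusted p = 0.675 with an estimated correlation), a fall not separated from the amount of somatic RNA carried over into the IP. The calls were 28 higher and 67 lower at 12h, 42 and 46 at 24h, and 68 and 109 at 48h. Without Stra8 IP 0 replicate 1 the totals of 95, 88 and 177 became 157, 138 and 355.

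At 4d, stem cell genes were lower in Stra8 IP RNA than at time 0. Gfra1, the GDNF co-receptor of stem cells, fell by 2.04 ± 0.18 (adjusted p = 4.53e-12, n = 2 each), Bcl6b by 1.60, Lhx1 by 1.45 and Eomes by 1.41, while Kit (1.79), Esx1 (2.15), Rhox13 (1.58) and Dmrtb1 (2.55 ± 0.51), which controls the switch from mitosis to meiosis, rose. Of 25 undifferentiated spermatogonia genes, 12 fell (median -0.89; adjusted p = 0.00401 with an estimated correlation), and 12 adjusted over the list alone. Somatic signal varied between arrays of a group: mean log2 intensity over the Sertoli cell list was 10.80 and 10.01 in the arrays at 4d, 9.57 and 10.37 at 24h, and 9.81 and 10.35 at time 0. The Sertoli cell list test (median 0.33, adjusted p = 0.000249; adjusted p = 0.773 with an estimated correlation) turned to -0.11 without Stra8 IP 4d replicate 1 and to -0.06 without Stra8 IP 0 replicate 1. Of 388 genes 169 were higher and 219 lower, and the total was 642 without Stra8 IP 4d replicate 2.

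At 6d genes of meiotic entry rose. Stra8 rose 11.8-fold over time 0 (log2 3.56 ± 0.38, adjusted p = 1.19e-10, n = 2 each), Rec8, the meiotic cohesin, by 2.14 ± 0.23, Meioc, which sustains meiotic prophase, by 2.93, Prdm9, which places recombination sites, by 2.80, and Ctcfl by 3.49. Cyp26a1 was raised again, by 1.46 ± 0.43 (adjusted p = 0.0059). Meiotic entry and prophase genes rose for 19 of 33 members (median 1.19, adjusted p = 8.32e-15; adjusted p = 0.201 with an estimated correlation) and differentiating spermatogonia genes for 10 of 16 (adjusted p = 0.239 with an estimated correlation). Etv5 (-1.96), Ret (-1.75), the GDNF receptor, and Shisa6 (-2.07) were among 11 undifferentiated spermatogonia genes that fell (median -0.92; adjusted p = 0.0125 with an estimated correlation). Over the same interval 14 of 31 Sertoli cell genes fell (median -0.76; adjusted p = 0.201 with an estimated correlation), with Amh at -2.28, Gja1 at -2.11 and Kitl at -1.76. Adjusted over the list alone, these counts were the same. The mean of the Sertoli cell list in Stra8 IP RNA was 10.08 ± 0.38 at time 0 and 9.15 ± 0.17 at 6d (SD, n = 2 each). Its fall may reflect how much somatic RNA was carried over into the IP, and a change within germ cells was not tested. Amh fell over the Stra8 total course too. In all, 739 genes were higher and 453 lower, a balance that quantile normalization moved to 572 and 531.

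At 8d, as at 6d, genes on the meiotic entry and prophase list stood above time 0. Meiob, which binds single-stranded DNA in meiotic recombination, rose 26-fold, from 68.9 ± 6.58 to 1791 ± 109 intensity units (SD, n = 2 each; log2 4.70 ± 0.16, adjusted p = 4.22e-28), and Spo11, which makes the double-strand breaks, by 4.00 ± 0.18. Terb1, which tethers telomeres, rose by 3.73 (2.44 at 6d) and Prdm9 by 3.19 (2.80 at 6d), and genes used later in spermatogenesis rose too: Ybx2 (2.71), a binder of stored mRNA, Ldhc (2.56), the germ cell lactate dehydrogenase, Hspa2 (2.37) and Acr (1.91), the acrosomal protease. Meiotic entry and prophase genes rose for 19 of 33 members (median 1.76; adjusted p = 0.107 with an estimated correlation) and pachytene and spermatid genes for 11 of 25 (median 0.83; adjusted p = 0.0425 with an estimated correlation). Undifferentiated spermatogonia genes fell for 17 of 25 members (median -1.33; adjusted p = 0.00273 with an estimated correlation), among them Pou5f1 (-2.05), Utf1 (-2.00) and Upp1 (-2.31). Piwil4 fell by 1.82. Sertoli cell genes stood lower for 8 of 31 members (median -0.70; adjusted p = 0.413 with an estimated correlation), which, as at 6d, may reflect how much somatic RNA was carried over. These counts held adjusted over the list alone. Calls numbered 873 higher and 600 lower, and the F test over the whole Stra8 IP course called 2155 genes, Meiob with an adjusted p of 3.09e-30.

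**Figure D2:**
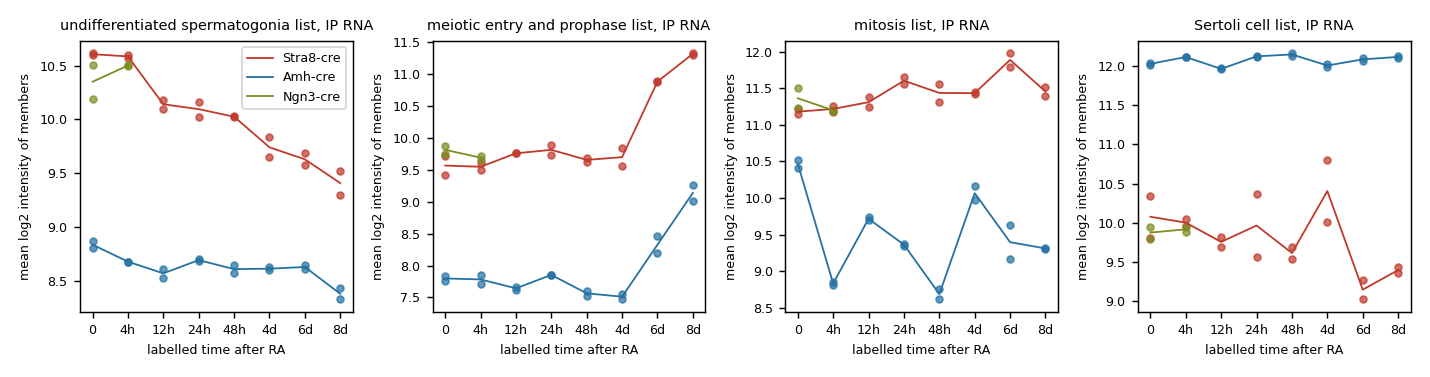
Mean log2 intensity of list members in IP RNA (vertical axes) against labelled time after RA for the undifferentiated spermatogonia, meiotic entry and prophase, mitosis and Sertoli cell lists; points are arrays, lines join group means, with Stra8 in red, Amh in blue and Ngn3 in green. In Stra8 IP the undifferentiated list goes from 10.61 at time 0 to 9.41 at 8d and the meiotic list from 9.56 to 11.31, with the Sertoli cell list at 10.08 and 9.40.

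Amh IP RNA asks how Sertoli cells respond. Genes of mitosis fell: Ccnb2, a cyclin of mitotic entry, was 12.5-fold lower at 48h (log2 -3.64 ± 0.15, adjusted p = 4.11e-24, n = 2 each) and fell by 1.74 at 24h, and Plk1, a mitotic kinase, fell by 2.71 at 48h, with Ccna2 at -2.75 and Depdc1a at -3.19. In the arrays labelled 4h Ccnb2 was at -3.24 ± 0.15 (adjusted p = 6.95e-22), Top2a at -2.16 and Plk1 at -2.20. Of 19 mitosis genes, 16 fell in the arrays labelled 4h (median -1.77; adjusted p = 0.000871 with an estimated correlation), 2 at 12h (median -0.74; adjusted p = 0.0739 with an estimated correlation), 11 at 24h (median -1.07; adjusted p = 0.000197 with an estimated correlation) and 17 at 48h (median -1.64; adjusted p = 8.2e-05 with an estimated correlation). In the arrays labelled 4d 0 of 19 passed (median -0.48; adjusted p = 0.383 with an estimated correlation), and 9 fell at 6d (adjusted p = 0.143 with an estimated correlation) and 9 at 8d (adjusted p = 0.237 with an estimated correlation). DNA replication genes fell for 2 of 20 members at 24h (median -0.58; adjusted p = 0.018 with an estimated correlation). Adjusted over the list alone, these counts were the same.

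Some RA target genes rose in Amh IP RNA at 12h, in the arrays labelled 4d and at later times. At 12h Tgm2 rose by 2.95 ± 0.25, Dhrs3, a retinaldehyde reductase induced by RA, by 1.95 and Rdh10, which makes retinaldehyde, by 2.75. In the arrays labelled 4d Rdh10 rose by 3.30 ± 0.49, Tgm2 by 2.28, Rarb by 1.53 ± 0.25 (adjusted p = 2.97e-05) and Lrat, which esterifies retinol, by 1.47. RA-induced targets rose for 6 of 18 members in the arrays labelled 4d (median 0.38, adjusted p = 2.78e-05; adjusted p = 0.0363 with an estimated correlation), for 4 at 12h (adjusted p = 0.0739 with an estimated correlation) and for 0 in the arrays labelled 4h (median 0.17, adjusted p = 0.685). Members also rose at 6d (4, adjusted p = 0.0684) and 8d (5, adjusted p = 0.111), where the list did not pass, with the same counts adjusted over the list alone. Rarb stood at 7.04 at time 0, 7.17 ± 0.01 in the arrays labelled 4h and 8.57 ± 0.01 in those labelled 4d (log2, SD, n = 2). Over the 56 genes that rose in Ngn3 IP RNA at 4h, the mean change from time 0 was 0.141 and 0.099 in the 2 Amh IP arrays labelled 4h, and 0.390 and 0.433 in those labelled 4d.

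Later in the Amh IP course Tmem255a (4.64 ± 0.50 at 8d, adjusted p = 1.26e-10), Bbox1 (4.13 ± 0.25 at 6d, 4.45 at 8d), the last enzyme of carnitine synthesis, and Slc15a1 (4.17 at 8d), a peptide transporter, rose. Gata1 rose by 1.43 at 6d and 1.36 at 8d, and Trf, the transferrin gene that mature Sertoli cells express, by 2.26 at 8d. Falling genes were Hsd17b1 (-3.17 at 6d, -3.54 at 8d), which converts sex steroids, Shisa6 (-3.83 at 8d), Gdnf (-1.46 at 6d), the stem cell growth factor, and Amh (-1.16 ± 0.31 at 8d, adjusted p = 0.00271). Meiotic genes rose in this fraction too, for 23 of 33 members at 8d over all genes and adjusted over the list alone (median 1.32; adjusted p = 0.237 with an estimated correlation), with Meiob at 2.83 ± 0.16 and Sycp3 at 2.36. At 48h the list of undifferentiated spermatogonia had a median of 0.01, which quantile normalization turned negative, and a mean of -0.23, and camera gave its direction as down (adjusted p = 0.00961; adjusted p = 0.798 with an estimated correlation). Counts of genes higher and lower were 124 and 263 in the arrays labelled 4h, 173 and 136 at 12h, 17 and 90 at 24h, 44 and 200 at 48h, 97 and 91 in the arrays labelled 4d, 252 and 427 at 6d, and 585 and 537 at 8d. The F test over the Amh IP time course called 1520 genes, of which 446 were called in the Stra8 IP course too, and 1429 genes without the arrays labelled 4h and 4d.

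The difference between the germ cell and Sertoli cell responses was tested directly, as the change in Stra8 IP minus that in Amh IP RNA at each time. Mitosis genes parted: they were higher in the Stra8 response for 17 of 19 members at 4h, against the Amh arrays labelled 4h (median 1.79; adjusted p = 0.00348 with an estimated correlation), 17 at 24h (median 1.45; adjusted p = 0.000521 with an estimated correlation) and 17 at 48h (median 2.01; adjusted p = 0.000211 with an estimated correlation). DNA replication genes were higher for 14 of 20 members at 12h (median 1.19; adjusted p = 0.0257 with an estimated correlation) and 10 at 48h (median 0.99; adjusted p = 0.0414 with an estimated correlation), with equal counts adjusted over the list alone. Largest differences over the course were 3.57 for Ccnb2, 3.18 for Ccna2 and 3.07 for Plk1, all at 48h, and -4.04 for Trf and -4.74 for Slc15a1, both at 8d. The largest differences of Cyp26a1 (2.52) and Rarb (2.08) rest on the Amh arrays labelled 4h, and that of Rdh10 (-3.40) on those labelled 4d, in which the acute RA response stood out of the labelled order. In the Stra8 versus Amh IP time course 3726 genes differed, and 3178 without the Amh arrays labelled 4h and 4d.

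Meiotic genes rose in whole-testis RNA of both lines. In Stra8 total RNA the largest changes over the course were rises of Fabp9 (4.80), Prss50 (4.38), Meiob (4.37), Crisp2 (4.35) and Dmc1 (3.56), the meiotic recombinase, and falls of Shisa6 (-3.06) and Amh (-2.81). Meiob started near the floor, at a log2 of 5.5 in Stra8 total 0 replicate 1 (5th percentile of that array 41.7 units), which limits the size of its change. In Amh total RNA Meiob (4.96), Prss50 (4.86), Terb1 (4.14), Tesmin (3.97) and Prdm9 (3.93) rose and Shisa6 (-3.06) and Amh (-2.28) fell. Meiotic entry and prophase genes rose for 28 of 33 members at 8d in Stra8 total RNA (adjusted p = 0.0165 with an estimated correlation) and for 29 in Amh total RNA (adjusted p = 0.0117 with an estimated correlation). Undifferentiated spermatogonia genes were lower for 6 of 25 members, with 1 higher, in Stra8 total RNA at 8d (median -0.57; adjusted p = 0.0492 with an estimated correlation). In Amh total RNA at 8d they were lower for 12 of 25, with 1 higher (median -0.87; adjusted p = 0.0111 with an estimated correlation). RA-induced targets rose for 6 of 18 members in the Amh total arrays labelled 4d (median 0.73; adjusted p = 4.78e-05 with an estimated correlation). All these list counts were unchanged adjusted over the list alone. The F tests called 1375 genes in Stra8 and 1528 in Amh total RNA.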

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

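The tests of the time labels of the Amh arrays and of the Stra8 IP arrays at 4d were chosen only after those results were seen; those of the meiotic genes were not.

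The time courses of 3726 genes differed between Stra8 IP and Amh IP, and with them the mitosis list at 4h (median difference 1.79, adjusted p = 0.00348 with an estimated correlation), 24h (1.451, adjusted p = 0.000521 with an estimated correlation) and 48h (2.013, adjusted p = 0.000211 with an estimated correlation). The DNA replication list differed at 12h (1.19, adjusted p = 0.0257 with an estimated correlation) and 48h (0.985, adjusted p = 0.0414 with an estimated correlation). The values at 4h rest on arrays whose label is in doubt.

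The acute RA response appeared in the Amh arrays labelled 4d and not in those labelled 4h. Over the 56 genes that rose in Ngn3 IP RNA at 4h, the lower Amh total array labelled 4d scored 0.841 above the higher Stra8 total one. Whole-testis RNA holds the same cells in both lines, so a late response common to both cannot account for that difference. The score does not single out Sertoli cells, as its genes were chosen in germ cell RNA. It was also higher in Amh total RNA labelled 4d (0.913 and 0.871) than in Amh IP RNA (0.390 and 0.433). A late response of Sertoli cells was therefore not tested apart from that of other cells. An exchange of the 4h and 4d labels in the Amh line may account for the pattern: the lower Amh IP array labelled 4d scored 0.249 above the higher one labelled 4h, and those labelled 12h (0.316 and 0.264) lay between. Median changes of the mitosis list ran in that order too: -0.48 in the arrays labelled 4d, -0.74 at 12h, -1.07 at 24h, -1.64 at 48h and -1.77 in those labelled 4h. By the mean log2 of the list, the arrays labelled 4h (8.831) lay above 48h (8.687). At 6d (9.396) and 8d (9.31) the mean was near that at 24h (9.362), so the fall did not continue. Scores of the Amh IP arrays at 6d (0.227 and 0.405) and 8d (0.292 and 0.424) were not separated from those labelled 4d. Amh total RNA at 4h was not analysed here. The undifferentiated spermatogonia list averaged 9.559 in Amh total RNA labelled 4d, near 9.549 at time 0 and above 9.279 at 24h. Stra8 total RNA at 4d averaged 9.198. The DNA replication list in Amh IP RNA averaged 9.687 in the arrays labelled 4d, 9.712 at time 0, 9.082 at 12h and 9.106 at 6d. These means argue against sampling at 4d, though the differentiating spermatogonia list in Amh total RNA (9.236) lay near 12h (9.282). An origin of the arrays labelled 4d other than an exchange stays open.

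Meiotic genes rose in Amh IP RNA at 8d. Over 23 called genes, the ratio of the rise in Amh IP to that in Amh total RNA had a median of 0.195 and quartiles of 0.165 and 0.225. The upper quartile of 0.225 lies below the lower quartile of 1.36 for the levels of the 31 Sertoli cell genes. Sertoli cells were thus not the only source of the rise in total RNA. Total RNA also holds germ cells, so a low ratio cannot exclude some transcription of these genes in Sertoli cells. Germ cell RNA carried over into the IP may account for the rise. The germ cell list (18 genes) had quartiles of 0.205 and 0.476 around a median of 0.298, all above the 0.195 of the meiotic genes. The rule for carry-over accepted any ratio within or below those quartiles, so a low ratio could not count against it. It also set a ratio of rises against ratios of levels.

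The Sertoli cell and macrophage lists stood higher in Stra8 IP RNA at 4d. All 5 somatic lists were higher in replicate 1 than in replicate 2, with median differences of 0.875 for Sertoli cell, 0.45 for Leydig cell, 0.703 for myoid, 0.989 for macrophage and 0.511 for endothelial genes, and the germ cell list differed by -0.243. The Sertoli cell list differed by about as much between the Stra8 IP arrays at 24h (9.57 and 10.37), and its 4d median also turned, to -0.055, without Stra8 IP 0 replicate 1. Somatic RNA carried over in amounts that varied between arrays may account for the 4d values, and no biological explanation was tested.

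Among the 57 tests for an array far from the other 3 of its group, 4 passed, and chance gives about 1 in 20. The test looked for 1 array apart from the rest, in groups of 4 only, and could not flag 2 arrays against 2. Stra8 total 24h, with 5th percentiles of 40.8 and 40.4 against 49.6 and 50.1, could thus go unflagged. Stra8 total 4h, a group of 3 with the lowest within-group r (0.958), was not tested. The meiotic entry and prophase list averaged 8.253 in Stra8 total 0 replicate 3, against 8.481 to 8.521 in the others. Sertoli niche factors averaged 9.397 in Stra8 total 0 replicate 2, against 9.472 to 9.486. Leydig cell genes averaged 9.938 in Stra8 total 0 replicate 1, against 9.741 to 9.764. Peritubular myoid genes averaged 10.303 in Stra8 total 48h replicate 4, against 10.203 to 10.216.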

How the results depend on the processing

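The settings that leave out the Amh arrays labelled 4h and 4d, the 3 arrays of narrow signal range or the Stra8 total arrays labelled 4h were chosen only after the results were seen. All 26 counts stayed within 1.5 times with the low-signal filter, the mean of a gene's probe sets, median centring, the compared groups alone and the replicate block, as did the 6, 3 and 2 counts rerun under the added settings, in that order. With the replicate block 376 list results kept their side of the threshold and 2 lost their call, Amh IP 12h versus 0, list endothelial (adjusted p = 0.0544) and Amh IP 8d versus 0, list Sertoli niche factors (adjusted p = 0.0532). With quantile normalization Ngn3 versus Stra8 4h response went from 0 to 2 genes and the other 25 counts stayed within 1.5 times. Without a fold minimum the counts, larger by construction, were 14219 for Stra8 IP versus total, 14782 for Amh IP versus total, 11097 for Ngn3 IP versus total, 13249 for Stra8 IP versus Amh IP and 3583 for Stra8 total versus Amh total. For Stra8 IP time course they were 11534 and, for Stra8 IP 4h versus 0, 329, Stra8 IP 12h versus 0, 916, Stra8 IP 24h versus 0, 1290, Stra8 IP 48h versus 0, 2370, Stra8 IP 4d versus 0, 4437, Stra8 IP 6d versus 0, 6668 and Stra8 IP 8d versus 0, 6846. For Amh IP time course they were 10627 and, for Amh IP 4h versus 0, 3047, Amh IP 12h versus 0, 2371, Amh IP 24h versus 0, 342, Amh IP 48h versus 0, 1816, Amh IP 4d versus 0, 1957, Amh IP 6d versus 0, 4600 and Amh IP 8d versus 0, 5601. Ngn3 IP 4h versus 0 had 410, Ngn3 versus Stra8 4h response 1, Stra8 versus Amh IP time course 13287, Stra8 total time course 13130 and Amh total time course 10855. Leaving out 1 array moved 12 of 310 counts, a lone array then being assumed to vary like the other groups. The ranges were 52 to 123 for Ngn3 IP 4h versus 0 and 0 to 41 for Ngn3 versus Stra8 4h response (both highest without Ngn3 IP 0 replicate 2), the latter moved in 7 of 8 fits. They were 74 to 157 for Stra8 IP 12h versus 0, 79 to 138 for Stra8 IP 24h versus 0 and 121 to 355 for Stra8 IP 48h versus 0 (each highest without Stra8 IP 0 replicate 1), and 359 to 642 for Stra8 IP 4d versus 0 (highest without Stra8 IP 4d replicate 2). Counted per gene, comparison and array left out, results of named genes kept their side of the threshold in 25131 cases, lost it in 308, gained it in 229 and reversed in 2. Both reversals were of Lyz2 (Stra8 IP time course: Lyz2 and Stra8 IP 4d versus 0: Lyz2), with a range of -0.081 (without Stra8 IP 4d replicate 1) to 2.15. A sign change between values that both miss the threshold counts as kept. With an estimated correlation 125 list calls were lost. Outside the course tests of total RNA and of Stra8 versus Amh IP, where others held too, those that held were germ cell, myoid and endothelial in Amh IP versus total, undifferentiated spermatogonia from 12h to 8d, RA-induced targets at 4h and 12h and pachytene at 8d in Stra8 IP, RA-induced targets in Ngn3 IP at 4h, mitosis at 4h, 24h and 48h, DNA replication at 24h and RA-induced targets at 4d in Amh IP. List medians that reversed, each given as its range over the arrays left out in turn, were -0.418 to 0.145 for Stra8 IP 4h versus 0, list Sertoli cell (reversed without Stra8 IP 0 replicate 2). For Stra8 IP 24h versus 0, list Sertoli cell, the range was -0.396 to 0.328 (reversed at 0.161 without Stra8 IP 0 replicate 2 and at 0.328 without Stra8 IP 24h replicate 1), and for Stra8 IP 24h versus 0, list Leydig cell and steroidogenesis, -0.309 to 0.2 (reversed without Stra8 IP 24h replicate 2). For Stra8 IP 4d versus 0 it was -0.111 to 0.782 for list Sertoli cell (reversed at -0.055 without Stra8 IP 0 replicate 1 and at -0.111 without Stra8 IP 4d replicate 1), -0.17 to 0.843 for list macrophage (reversed without Stra8 IP 4d replicate 1) and for Stra8 IP 4d versus 0, list Leydig cell and steroidogenesis, -0.287 to 0.285 (reversed without Stra8 IP 4d replicate 2). For Amh IP 12h versus 0, list undifferentiated spermatogonia, it was -0.1 to 0.015 (reversed without Amh IP 12h replicate 1). For Amh IP 48h versus 0, list undifferentiated spermatogonia, it was -0.015 to 0.014 (reversed at -0.007, -0.001 and -0.015 without Amh IP 0 replicate 1, Amh IP 48h replicate 1 and Amh IP 48h replicate 2), and quantile normalization gave -0.044. For Amh IP 4d versus 0, list immediate early, it was 0 to 0.142 (0 without Amh IP 0 replicate 1), and for Ngn3 versus Stra8 4h response, list Sertoli cell, -0.17 to 0.37 (reversed without Stra8 IP 0 replicate 2). For all of these the cause was not tested. Low signal limits genes near the floor, as the 5th percentile lay at 39.3 to 50.1 units and array medians at 252.6 to 300.5.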

Other observations

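The comparison of Ngn3 total RNA at 4h with time 0 and the look at signal ranges were chosen only after the results were seen; the splits were planned.

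Whole-testis RNA of the Ngn3 line differed from time 0 at 4h after RA, with no vehicle-injected arrays to set against it. Rdh10, which makes retinaldehyde, rose by 2.62 ± 0.49 (adjusted p = 0.000833, n = 2 each), Fstl3, an inhibitor of activin, by 2.56 ± 0.47, Esyt3 by 2.42, Cidea, a lipid droplet protein, by 2.10, Nags by 1.89 and Cyp26a1 by 1.85 (adjusted p = 0.0124). In all, limma called 50 genes higher and 10 lower. Rdh10 and Esyt3 were also among the genes that rose in Amh IP RNA, Rdh10 by 2.75 and Esyt3 by 3.16 at 12h.

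Genes enriched by each tag were among those called over the time courses. Of 220 genes enriched in Amh IP over total RNA, 92 changed over the Amh IP course (41.8%) and 53 over the Stra8 IP course (24.1%). Of 766 genes enriched in Stra8 IP over total RNA, 212 changed over the Stra8 IP course (27.7%) and 138 over the Amh IP course (18%). Of all genes tested, 10.8% were called over the Stra8 IP course and 7.62% over the Amh IP course, and no share was tested against another. At 8d, 111 genes rose in both IP fractions (25.6 expected by chance) and 97 fell in both (16.2 expected). The shared rises hold meiotic genes, for which germ cell RNA carried over into the Amh IP may account (median ratio of 0.195).

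Over the 56 genes that rose in Ngn3 IP RNA at 4h, Stra8 total 4h replicate 1 scored 0.327, and replicates 2 and 3 scored -0.045 and -0.092. The germ cell and piRNA pathway list had a mean of 9.27 in replicate 1, the lowest of the Stra8 total arrays, and of 10.245 and 10.131 in replicates 2 and 3, against 9.579 to 9.801 at 0, 9.528 to 10.08 at 24h, 9.864 to 10.05 at 48h, and 10.224 and 10.193 at 4d. On the third principal component they lay at 0.086 and 0.05, beside the Stra8 total arrays labelled 4d (0.061 and 0.052) and away from replicate 1 (-0.11), and which of the 3 arrays departs in cell content or label stays open. Without the Stra8 total arrays labelled 4h, the calls were 1930 for Stra8 IP versus total and 1370 for Stra8 total time course, against 1837 and 1375. In Ngn3 total RNA at 4h the scores were 0.679 and 0.68, over genes not chosen in that fraction. Stra8 total 4h replicate 1 and 24h replicates 3 and 4 had a narrower signal range than the other 74 arrays, with 5th percentiles of 49.2 to 50.1 against 39.3 to 43.3, and upper quartiles of 809 to 833 against 920 to 1102. On the fourth principal component other Stra8 total groups split too. Time 0 lay at -0.113 and -0.087 against 0.066 and 0.103, and 48h at 0.062 and 0.071 against -0.121 and -0.118. Both arrays at 12h were positive (0.147 and 0.107). The labels name no batch, and such a split cannot be told apart from part of the change over the Stra8 total course.

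With single arrays exchanged between the arms, 1 of 100 splits, the real one, gave as many genes in Stra8 IP against total (1837, highest other 389), in Amh IP against total (1005, highest other 408, or 224 with swaps within pairs), in Stra8 against Amh IP (3349, highest other 1609) and in Stra8 against Amh total RNA (6, highest other 1). Where the arms differ strongly, a false split mixes unlike arrays and widens the spread, so fewer calls were likely beforehand. The labels do not say that arrays came from separate animals, so chance between animals or preparations is not excluded. Counts for single times were not split. For Ngn3 IP against total the 18 splits are too few for a share under 0.05, and the real count was 2578 against 261 for the highest other.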
